A study of Mus musculus with 9 samples.

How the data were processed

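Spinal cord total RNA from 9 samples of C57BL/6 mice was measured by RNA sequencing on day 7, with 3 libraries each of control, injury and HBO cord. The labels describe the control samples as uninjured, while the series design speaks of sham animals, so whether they were operated on is not settled here. The submitters' processing notes name HISAT2 and the GRCm38 build; the version of HISAT2, the counting program, and the handling of strand and multiple hits are not given in the sources used here. Per the file headers, the authors deposited a count and an FPKM value for each long noncoding transcript in each library. The deposited counts are whole numbers, not normalized. The deposited FPKM values are scaled by transcript length and by a library total, of which the 2295433 to 3148744 counts of the listed transcripts made up 17.1% to 19.5%.

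The 69547 transcripts comprised 62343 with NONCODE, 6736 with Ensembl and 468 with MSTRG identifiers. Counts were summed per Ensembl gene name, which left 67924 features, and the others stayed single. Positions were taken from the files and set beside GENCODE M21, where 97.1% of the matched Ensembl transcripts had the same start and end. Each feature was classed by its whole span, without regard to strand, as touching a coding exon, inside a coding intron, or intergenic. Because the files list noncoding RNAs only, the comparisons planned for all genes and for long noncoding genes were the same and are reported once.

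All 9 libraries entered one fit by group with edgeR 4.0.16 in R 4.3.3 (filterByExpr with a minimum count of 10, TMM scaling, glmQLFit and glmQLFTest), and a Benjamini-Hochberg adjusted p under 0.05 was called. Log2 fold changes carry standard errors from the test statistic, and CPM values carry the SD over 3 libraries. The fit and its filter, 43 gene lists with 645 genes, the named-gene rule and most alternatives were fixed before the data were examined. Few list members are noncoding genes. After the files were seen, counts of transcripts whose span overlapped a coding gene were therefore summed per gene. Lists with at least 5 tested members were tested on these host-gene sums. Lists were tested by camera of limma 3.58.1 with a preset correlation of 0.01, and again with an estimated correlation and with fry. Named features were the 8 largest changes each way among called features at 5 CPM or more whose groups did not overlap, the 5 largest each way at 1 CPM, and up to 2 called members each way per list, or the 2 with the smallest p where none passed; for HBO against control, 4 each way were named.

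Alternatives were RLE scaling, no filter, DESeq2 1.42.0, a replicate block, fits on the 2 groups compared, transcripts as listed, a minimum log2 change of 1, and leaving out each library. Library totals from the FPKM values, a robust fit, merged overlapping transcripts and features away from coding exons were added later. The fit was tested on simulated counts for 26602 features with known changes. In injury against control it recovered 0 of 100 features at 2-fold and 39 of 100 at 4-fold, with 2 false among 41 calls. For HBO against injury it recovered 0 and 39, with 5 false among 44 calls. For HBO against control it recovered 2 and 26, with 3 false among 31 calls. Counting error alone sets the bounds given for groups with 0 counts. Replicates were compared with each other, and none agreed within sampling noise (chi-square per degree of freedom 7.35 to 20.2). Lists with fewer than 5 tested members were not tested as lists. Some genes that the naming rule selects are not reported here.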

Results

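The spinal cords of C57BL/6 mice were sampled on day 7 in 3 groups of 3 libraries each: cord without injury (control), cord after spinal cord injury (injury), and injured cord of animals given hyperbaric oxygen, which is oxygen breathed above atmospheric pressure (HBO). Total RNA was sequenced, and the deposited counts covered 69547 long noncoding transcripts in every library. The counts summed to between 2295433 in HBO replicate 3 and 3148744 in injury replicate 1, which was between 17.1% and 19.5% of the library totals recovered from the FPKM values. Nothing states that replicates came from separate animals, so the p-values measure the spread between these libraries, which may be technical. On principal components of log2 CPM, the counts scaled to a common library size, the control libraries lay apart from the other 6 on the first component, and HBO replicate 3 lay apart from the other 8 on the second.

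**Figure D1:**
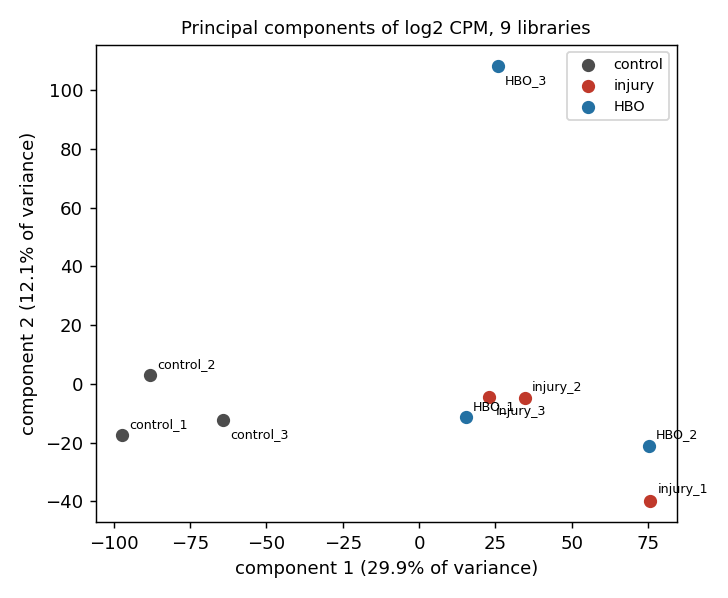
Position of each of the 9 libraries on the first component (29.9% of variance) and the second component (12.1% of variance) of log2 CPM, coloured by group. The 3 control libraries have negative values on the first component, the injury and HBO libraries lie together on the positive side, and HBO replicate 3 stands at 108 on the second component.

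The first comparison, injury against control, asked how the injured cord differed from uninjured cord. H19, an imprinted long noncoding RNA of fetal tissues, rose from 29.8 ± 3.61 CPM in control to 387 ± 207 CPM in injury (SD, n = 3). Dnm3os, the precursor of miR-199a and miR-214, rose from 1.23 ± 1.12 to 95.2 ± 55.6 CPM. Snhg14, which runs through the Ube3a locus, fell from 1308 ± 136 to 699 ± 111 CPM, and Rian, a maternally expressed RNA of the Dlk1-Dio3 locus, fell from 1267 ± 119 to 797 ± 57.6 CPM. The log2 changes were 3.70 (SE 0.55, adjusted p = 0.0169) for H19, 6.19 (SE 0.76, adjusted p = 0.0145) for Dnm3os, -0.90 (SE 0.19, adjusted p = 0.0354) for Snhg14 and -0.67 (SE 0.13, adjusted p = 0.0306) for Rian, by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. Where transcripts with overlapping spans were summed, the log2 change of Dnm3os was 1.83 and that of H19 was 3.47. Of 40 tested members of the list of known long noncoding RNAs, 4 rose, 2 fell and 34 did not pass; adjusted over the list alone, 9 rose and 5 fell. The list as a whole rose by camera with a preset correlation (adjusted p = 0.0420), and the adjusted p = 0.0949 with an estimated correlation. That call was also lost without control replicate 1 (adjusted p = 0.0634), control replicate 2 (adjusted p = 0.0923) or injury replicate 2 (adjusted p = 0.0619).

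Several of the transcripts without a common name had 0 counts in each library of one group. NONMMUT068776.2 (chromosome 9, 43045840 to 43050998, GRCm38, inside an intron of Arhgef12) had 0 counts in control and 54.8 ± 4.48 CPM in injury, at least 145-fold higher (adjusted p = 5.6e-05, edgeR). RP23-380L19.3 (chromosome 6, 5216258 to 5220486, 366 bp from Pon3) rose from 0.132 ± 0.229 to 158 ± 42.3 CPM. NONMMUT001471.2 (chromosome 1, 72858067 to 72859857, on the UTR of Igfbp5) rose from 2.01 ± 0.371 to 2253 ± 737 CPM. NONMMUT052555.2, on the UTR of Rbm47, was at least 96.8-fold higher. NONMMUT031640.2 near Rnf125 was at least 33.0-fold higher, with 27.3, 6.94 and 3.32 CPM in injury replicates 1, 2 and 3. NONMMUT105282.1 had 0 counts in control and 6.06 ± 2.11 CPM in injury, while NONMMUT057027.2 near Cpvl and NONMMUT092674.1 rose by log2 changes of 7.38 and 6.89. Injury replicates 1, 2 and 3 had 134, 21.6 and 41.3 CPM of NONMMUT092674.1. In the other direction, NONMMUT110693.1 on chromosome 3 had 18.1 ± 1.41 CPM in control and 0 counts in injury, at least 47.8-fold lower. NONMMUT100183.1 (chromosome 16, 75184085 to 75188832, intergenic) was at least 44.2-fold lower, and NONMMUT037654.2, across Scn9a, at least 24.5-fold lower. NONMMUT050210.2 on the UTR of Camk2n1 had 299 ± 31.4 CPM in control and 0.756 ± 0.0164 CPM in injury, and NONMMUT057857.2 on the UTR of Rab7 had 114 ± 76.8 and 0.378 ± 0.00820 CPM. Both were uneven within the HBO group, as were NONMMUT057027.2, NONMMUT001471.2 and NONMMUT052555.2 among others. In HBO replicates 1, 2 and 3, NONMMUT050210.2 had 127, 0.836 and 0.809 CPM and NONMMUT057857.2 had 27.6, 0.418 and 37.2 CPM. NONMMUT057027.2 had 19.8, 0 and 0.809 CPM there, NONMMUT001471.2 had 2.33, 1998 and 1161 CPM, and NONMMUT052555.2 had 4.66, 43.9 and 38.4 CPM. NONMMUT086701.1, NONMMUT095524.1 and NONMMUT105487.1 were at least 21.8-fold, 16.5-fold and 15.4-fold lower. Each bound sets 3 counts over the group against the 0 counts, and covers counting error only.

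Of 26602 features tested by edgeR, 965 rose and 646 fell (1611 in all), and 765 and 366 of these changed at least 2-fold. With library totals from the FPKM values in place of TMM scaling, which moved the median log2 change by -0.22, 644 rose and 1364 fell. The count was 39, 34 and 467 without control replicates 1, 2 and 3, 110, 209 and 680 without injury replicates 1, 2 and 3, and 1042 without HBO replicate 1. Of 50 named features and host genes that passed here, 2 passed in every setting in which they were refitted and none changed direction there.

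**Figure D2:**
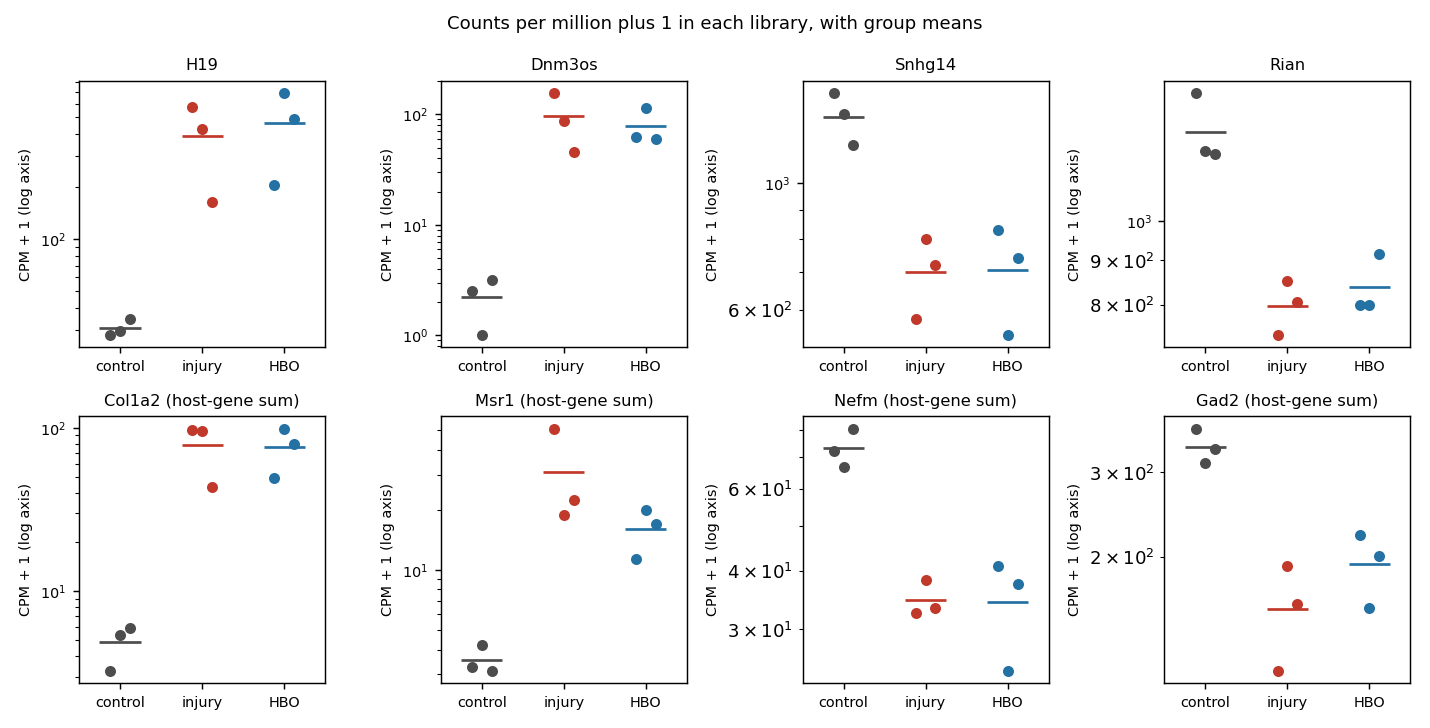
CPM plus 1 on a log axis in each library (points) with group means (lines) for H19, Dnm3os, Snhg14 and Rian. The other panels give the summed noncoding transcripts overlapping Col1a2, Msr1, Nefm and Gad2. H19 averaged 29.8 CPM in control and 387 CPM in injury, and Gad2 sums averaged 339 and 155 CPM.

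Counts of noncoding transcripts whose span overlapped a protein-coding gene were also summed per coding gene, here called its host-gene sum. Of 10 sums of genes that mark fibroblasts and collagen scar, 5 rose and 5 did not pass, with a median log2 change of 1.90 (adjusted p = 0.209 with an estimated correlation). Among those that passed, Col1a2, a chain of type I collagen, rose by 4.31 (SE 0.45) and Postn, a matrix protein, by 3.56 (SE 0.88). Of 9 sums of apoptosis genes and p53 targets, 4 rose, among them Bcl2l11, a BH3-only death factor, by 2.14 (SE 0.35) and Casp8, an initiator caspase, by 1.81 (SE 0.34). Of 6 sums of lysosome and lipid-handling genes, 2 rose: the cholesterol exporter Abca1 by 2.12 and the protease Ctsd by 2.11. Of 6 sums of chondroitin sulphate proteoglycan genes, 1 rose, Vcan, by 1.18. In the same libraries, sums of 12 genes of excitatory and inhibitory transmission had a median log2 change of -0.81 and 3 fell, including the AMPA receptor gene Gria2 (-1.37) and the GABA-synthesis gene Gad2 (-1.13). Of 8 sums of neuronal genes, 4 fell, including the neurofilament gene Nefm (-1.10) and the synaptic vesicle gene Syt1 (-0.94). Adjusted over the list alone, 9 fibroblast, 8 apoptosis, 4 lysosome and 3 proteoglycan sums rose, and 7 transmission and 4 neuronal sums fell.

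These 6 of 16 lists passed by camera with a preset correlation, 4 upward and 2 downward: fibroblasts (adjusted p = 5.6e-08), apoptosis (2.9e-05), lysosome (4.3e-05), proteoglycans (0.0153), transmission (5.5e-05) and neurons (0.00269). With an estimated correlation none of the 6 passed: adjusted p = 0.209 with an estimated correlation for the first 5 and adjusted p = 0.288 for neurons. The other 10 lists did not pass by camera. By fry, which does not compare a list with other genes, 8 lists passed, among them autophagy (adjusted p = 0.00587) and antioxidant enzymes (adjusted p = 0.0339). Among the 10 lists that did not pass by camera, median log2 changes were -0.65 for myelin (5 sums, 0 passing) and -0.51 for cholesterol synthesis (7 sums, 0 passing). Medians were 0.61 for angiogenesis, 0.53 for antioxidant enzymes, 0.36 for autophagy, 0.32 for the hypoxia response and 0.31 for axon growth inhibitors. Astrocyte homeostasis had a median of 0.03, neurotrophic factors -0.03 and the inflammasome -0.10. Whether reads were counted by strand is not given, so reads of a noncoding transcript were not separated from those of messenger RNA overlapping it. Transcripts on coding exons may share reads with that messenger RNA, and such sharing was not measured. On sums without transcripts on coding exons, the apoptosis, transmission and neuron lists passed (adjusted p = 0.000208, 0.00117 and 0.00593), though not with an estimated correlation (adjusted p = 0.178 for each). The other 3 lists had fewer than 5 members there and were not tested.

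Single host-gene sums outside the lists that passed by camera also changed. Some belonged to tested lists that did not pass by camera, and others to lists with too few tested members. The macrophage genes Msr1, a scavenger receptor, and Spp1, osteopontin, rose by log2 changes of 3.54 (SE 0.48) and 3.06 (SE 0.51), while the third tested gene of that list, Gpnmb, had a log2 change of -2.40 (adjusted p = 0.343). B2m, the light chain of MHC class I, rose by 1.76, the NADPH oxidase subunit Cyba by 2.05 and Irak4 by 2.43. The Irak4 sums in control replicates 1, 2 and 3 were 1.13, 2.39 and 6.40 CPM. Nrp1 rose by 1.17, Angpt2 by 0.77, Nek7 by 1.00, Atg7 by 0.89, Tfeb by 0.88, Txnrd1 by 0.86, Bcas1 by 0.51 and Drp2 by 1.19. Slc1a3, an astrocyte glutamate transporter, rose by 0.93, whereas Sod2 fell by 0.62 and Nrg1 fell by 0.80. Sums of the reactive astrocyte genes Ptx3 (1.36) and S1pr3 (0.32), of the cytokines Il1b (-0.24) and Il1a (-0.06) and of the myelin gene Mog (-0.69) did not pass. Over all 6595 host genes tested, 538 rose and 162 fell.

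**Figure D3:**
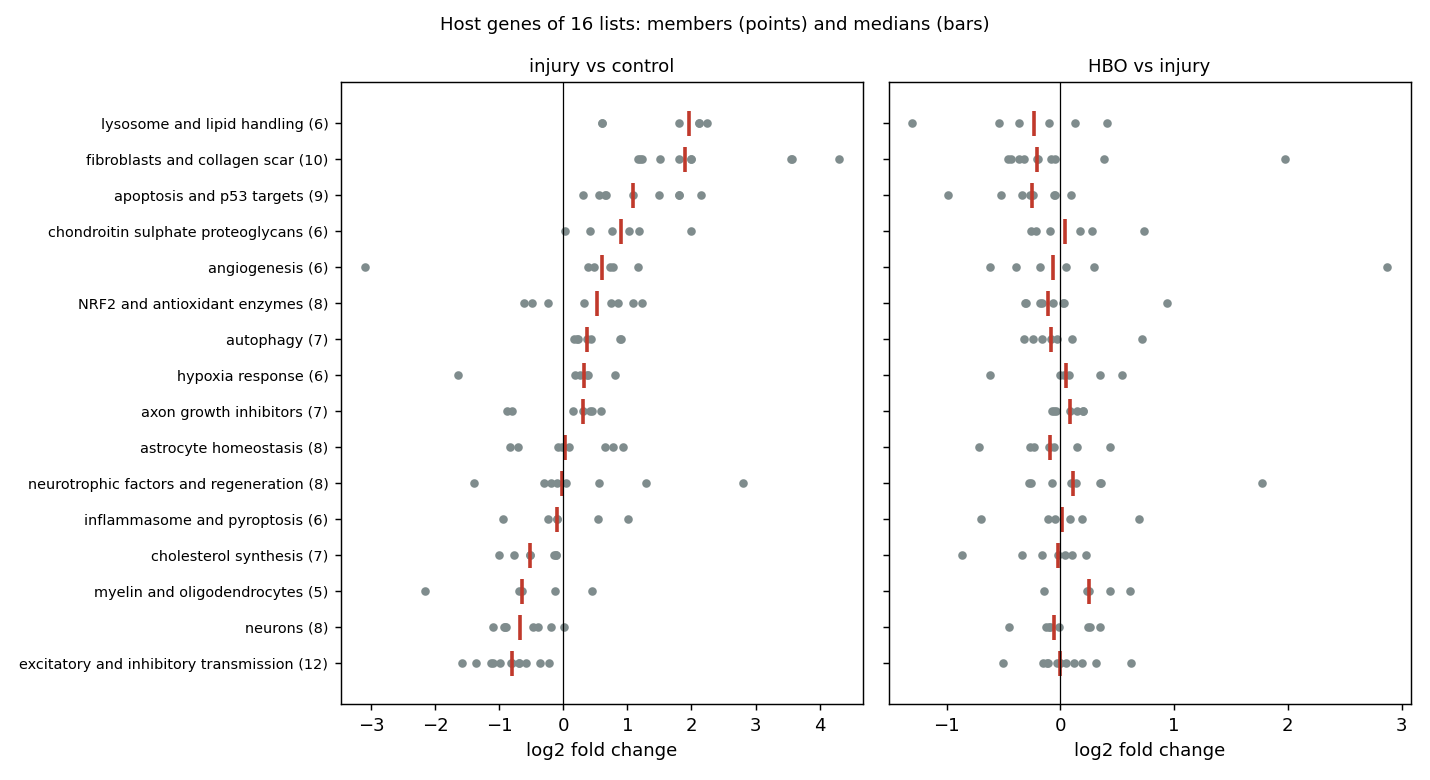
Log2 fold changes of host-gene sums in 16 lists fixed beforehand, with injury against control on the left and HBO against injury on the right (points, members; bars, list medians; number of members in parentheses; the axes differ in range). In injury against control the medians run from 1.96 for lysosome and lipid handling to -0.81 for transmission, and in HBO against injury no member passed.

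The second comparison, HBO against injury, addressed the effect of the treatment on the injured cord. A transcript on the UTR of Ide, the insulin-degrading enzyme gene, NONMMUT034612.2 (chromosome 19, 37268974 to 37270710), was at 119.7 ± 16.5 CPM in HBO and 4.17 ± 0.731 CPM in injury, with 98.8 ± 16.7 CPM in control. NONMMUT100183.1, the intergenic transcript absent from the injury libraries, was at 7.39 ± 1.36 CPM in HBO, at least 19.6-fold higher. NONMMUT086510.1 (chromosome 12, 21558383 to 21564177, intergenic) had 36.6 ± 10.3 CPM in injury and 0 counts in HBO, at least 90.8-fold lower. NONMMUT069202.2 (chromosome 9, 54947749 to 54949913, on the UTR of Hykk) fell from 21.5 ± 3.29 to 2.15 ± 0.938 CPM, where control had 1.15 ± 0.431 CPM. The adjusted p-values by edgeR's quasi-likelihood test were 0.000142, 0.0388, 0.00290 and 0.0388 in that order, and the log2 change at Ide was 4.83 (SE 0.24).

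These 4 of 26602 features, 2 higher and 2 lower, were all that passed, while 966 had an unadjusted p under 0.05 and DESeq2 called 55. Of the 15 settings in which these transcripts were refitted singly, NONMMUT034612.2 passed in all and NONMMUT086510.1 in all but the fit on the libraries of the 2 groups alone, while NONMMUT100183.1 was lost in 7 and NONMMUT069202.2 in 11. The count rose to 19, 15 and 17 without injury replicates 1, 2 and 3 and to 9, 15 and 14 without HBO replicates 1, 2 and 3, and was 2 without control replicate 3. Simulated 2-fold changes were recovered for 0 of 100 features and 4-fold changes for 39 of 100, with 5 false among 44 calls.

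**Figure D4:**
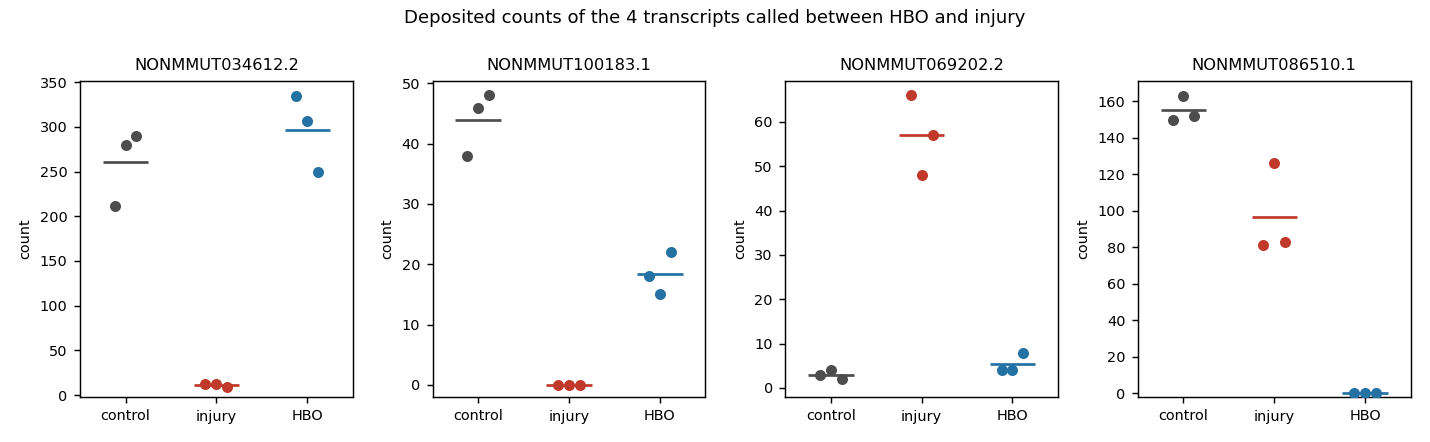
Deposited counts in each library (points) with group means (lines) for the 4 transcripts that passed between HBO and injury. NONMMUT034612.2 has 9 to 12 counts in the injury libraries and 249 to 335 in the HBO libraries, and NONMMUT086510.1 has 0 counts in each HBO library.

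No list and no list member passed in HBO against injury; adjusted over the list alone, 1 member passed, the autophagy gene Atg12 (log2 change 0.72, SE 0.20). The known long noncoding RNAs had a median log2 change of -0.04 (camera adjusted p = 0.178), with Trp53cor1, the p53-induced RNA next to Cdkn1a, at -0.82 (SE 0.31) and Hotairm1 at -1.46 (SE 0.70). Where transcripts with overlapping spans were summed, Hotairm1 stood at 0.38 and also did not pass. Host-gene sums that rose with injury had values on both sides of 0: Col1a2 -0.05, Msr1 -0.98, Spp1 -0.98, Ctsd -0.37 and B2m 0.30. Sums that fell with injury had values of 0.62 for Gria2, 0.32 for Gad2, -0.01 for Nefm and -0.10 for Syt1. The antiviral gene Mx1 (1.30, SE 0.48) did not pass. Of 16 host-gene lists, 0 passed by camera with either correlation or by fry, and unadjusted p under 0.05 was reached by 1 list by camera, apoptosis (median log2 change -0.25), and by 1 list by fry, neurotrophic factors (median 0.11). Without HBO replicate 2, 2 host-gene lists passed downward, and the known long noncoding RNAs passed downward (camera adjusted p = 0.0498).

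The third comparison, HBO against control, asked what differed from uninjured cord in the treated group. H19 rose by a log2 change of 3.95 (SE 0.55) and Dnm3os by 5.90 (SE 0.76), while Snhg14 (-0.89) and Mir124a-1hg (-1.26), a host of the neuronal miR-124, fell. Of 10 fibroblast and scar sums 3 rose, including Col1a1 by 5.52 (SE 1.19) and Col1a2 by 4.26. The Col1a1 sums were uneven in control, at 25.9, 0.798 and 67.5 CPM in replicates 1, 2 and 3. Abca1 and Ctsd rose by 2.02 and 1.75, Bcl2l11 and Casp8 by 1.87 and 1.47, and Vcan and Xylt1, a proteoglycan-synthesis gene, by 1.09 and 0.59. In the same libraries Nefm (-1.11), Syt1 (-1.04), Gria1 (-0.86) and Gad2 (-0.81) fell. Adjusted over the list alone, 7 fibroblast, 3 apoptosis, 3 lysosome and 3 proteoglycan sums rose, and 7 transmission and 5 neuronal sums fell.

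Msr1 (2.56), Spp1 (2.08), B2m (2.07), Cyba (1.90) and Mx1 (2.35) also rose in HBO against control. NONMMUT068776.2, inside Arhgef12, was at least 133-fold higher than in control, and RP23-380L19.3, NONMMUT052555.2 and NONMMUT001471.2 were higher as well, though HBO replicate 1 had 2.33 CPM of NONMMUT001471.2. NONMMUT086510.1 was at least 146-fold lower, and NONMMUT056987.2 and NONMMUT073505.2, the latter in the Ftx locus, were at least 18.6-fold and 15.6-fold lower. NONMMUT136504.1 had 6.44 ± 3.28 CPM in control and 0 counts in HBO. Of 26602 features 771 rose and 369 fell by edgeR (1140 in all); with library totals from the FPKM values, which moved the median by -0.16, 450 rose and 398 fell. The count was 20, 20 and 272 without control replicates 1, 2 and 3, 156 and 350 without injury replicates 2 and 3, and 667, 66 and 281 without HBO replicates 1, 2 and 3. The same 6 host-gene lists passed by camera, 4 upward and 2 downward, and none did with an estimated correlation (lowest adjusted p = 0.228 with an estimated correlation); fry called 8.

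Of the 1611 features that changed with injury, 3 changed back in HBO: NONMMUT034612.2, NONMMUT100183.1 and NONMMUT069202.2, the last 2 being among the less stable calls above. Independent lists, which leave out that both comparisons share the injury libraries, would share 0.121. Simulated HBO libraries with no treatment effect gave a median of 0 and at most 2. Of the 10 splits of the injury and HBO libraries, 7 gave as many, the real one included, and the highest other gave 8. The 3 are therefore not shown to exceed what other splits of these libraries give. The count of features changed back was 16, 11 and 15 without injury replicates 1, 2 and 3, 5 without HBO replicate 2 and 1 without control replicate 3. Over those 1611 features, the HBO change from control was a median of 0.886 times the injury change. Simulated libraries without an HBO effect gave a median of 0.888 (range 0.874 to 0.901), with 18 of 50 simulations as low as observed. These simulations drew each feature independently, so their range leaves out shifts of whole libraries. The likeness of the medians therefore does not show that HBO was without effect. Single HBO libraries gave ratios of 0.776, 1.06 and 0.797, and single injury libraries set against the other injury libraries gave 1.28, 0.920 and 0.838. Features that passed in both injury and HBO against control in the same direction numbered 808, where independent lists would share 36.9. Simulated groups with no effect shared a median of 0 and at most 1, but the adjusted threshold lets few features pass where nothing changes. That value therefore does not measure what the shared controls add where many features change. Part of the excess over independent lists may come from those controls. Simulated HBO libraries like the injury libraries shared a median of 1694. That is more than the 1611 real injury calls, so the simulation gave more calls than the data, and the 808 cannot be weighed against it. The changed-back count and the ratio were set against these same simulated libraries, so that limit holds for them too.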

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

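Host-gene lists, library totals from FPKM, the robust fit, merged transcripts and features away from coding exons were tests chosen after seeing the data; the other settings were planned. The count of changed features in injury against control (1611) was 308 without a filter, 3676 with DESeq2 and 2432 with overlapping transcripts merged, and 34 to 1814 with one library left out. HBO against injury (4) gave 55 with DESeq2, 2 with library totals from FPKM, 2 away from coding exons and 2 to 19 with one library left out. HBO against control (1140) gave 204 without a filter, 3081 with DESeq2, 331 on the 2 groups alone, 1806 with transcripts merged and 20 to 1037 with one library left out. Fewer samples and, without a filter, more features tested enter these fits; the cause was otherwise not tested. RLE scaling gave 1611, 4 and 1137, and the robust fit 2108, 4 and 1535. The known long noncoding RNA list in injury against control (1 call) gave 0 with an estimated correlation and 0 to 1 with one library left out, and 0 to 1 in HBO against injury. Host-gene lists (6 in injury and 6 in HBO against control) gave 0 and 0 with an estimated correlation and 3 and 3 without transcripts on coding exons; in HBO against injury they gave 0 to 2 with one library left out. The cause was not tested. The 3 features changed back were 1 with library totals from FPKM and 1 to 16 with one library left out; the median ratio stayed between 0.762 and 0.962 with one library left out. No named feature that passed changed sign in the settings in which it was refitted, but library totals from FPKM turned the injury calls from 965 higher and 646 lower to 644 and 1364. Of the named features that passed, 2 of 50, 1 of 4 and 3 of 39 passed in every setting in which they were refitted singly, which leaves out the robust, merged, transcript-level and away-from-coding-exon fits. With 2295433 to 3148744 counts a library, simulated 2-fold changes were recovered for at most 2 of 100 features, where few features changed; with many changed, as after injury, smaller changes passed.

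With the replicate number as a replicate block, 7, 2 and 9 features passed in injury against control, HBO against injury and HBO against control, and 1 feature changed back; host-gene list calls stayed at 6, 0 and 6. Correlations of deviations between same-numbered libraries ran from -0.054 to 0.052 over 9 pairs, and 2 of 9 libraries correlated best with their own number, so the numbers do not pair the samples.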

Other observations

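The tests of transcripts switching between libraries, of coding-exon reads and of the neuronal share were chosen after the results were seen, as were the comparison of interferon genes library by library and the exact interval for the second transcript inside Ide. Some transcripts were near 0 in single libraries and abundant in others of the same group. Kcnq1ot1, the antisense RNA of the Kcnq1 imprinted domain, had 0 counts in injury replicate 1 and 5532 to 8541 in the other 8 libraries. Gm26917 had 104 counts in HBO replicate 3 and 90440 to 196022 elsewhere. It is listed together with a second transcript of 45S ribosomal RNA. Their joint share of the counts was 6.76% in HBO replicate 3, against 6.68% to 9.86% elsewhere. The low count of Gm26917 therefore does not show a loss of that RNA in HBO replicate 3. The 7SL share of the counts was 3.77% there against 5.19% to 17.2%. Of 12951 features reaching 50 counts in a library, 988 (7.63%) had 5 or fewer in another library of the same group. The share was 15.3% on coding exons, 1.83% in introns and 9.73% between genes.

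The first pattern is the 4 transcripts that passed between HBO and injury, each at 12 counts or fewer in every library of at least one group. A like change of both listed transcripts inside Ide is argued against: the other one, in an intron, had 13 counts in injury and 9 in HBO, a log2 ratio of -0.44 (95% exact interval -1.84 to 0.90, for counting error only), below 2.42, the midpoint between no change and the 4.83 of NONMMUT034612.2, though Ide messenger RNA itself was not measured. Transcripts switched together were counted in each of the 84 sets of 3 libraries, and 66 sets had as many as the larger of the injury and HBO sets, which had 1 each. The control set had 7, above the 5 of the highest mixed set. Such switching may therefore account for single calls, and it cannot be told apart from a treatment effect on the transcript at Ide.

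The second pattern is the opposite movement of scar and neuronal host-gene sums after injury. On sums without transcripts on coding exons, the apoptosis, transmission and neuron lists had median log2 changes of 1.04, -0.65 and -0.56. These 3 still passed by camera with the preset correlation there. As for all 6 lists on the full sums, they did not pass by camera with an estimated correlation (adjusted p = 0.178). On the full sums, the preset test also called up to 5 lists in mixed splits of the injury and control libraries. Whether reads of messenger RNA on coding exons were the whole cause for these lists therefore stays open. Singly, 3 of 7 apoptosis sums without such transcripts rose, and 2 of 10 transmission and 2 of 6 neuronal sums fell. Reads of unspliced RNA of the same coding genes would stay in the sums without coding exons. A change of the coding genes themselves is therefore not excluded. For the fibroblast, lysosome and proteoglycan lists the part of exon reads also stays open, because all 3 had under 5 members on the sums without coding exons. There, 4 of 4 fibroblast, 1 of 2 lysosome and 2 of 3 proteoglycan sums tested rose singly. A lower share of neuronal RNA alone would raise other cell types alike, but the fibroblast median exceeded the astrocyte homeostasis median by 1.87 (95% bootstrap interval 0.855 to 3.52). Genes were resampled, not libraries, so the interval treats the genes of a list as independent. It does not cover the spread between libraries. The pair of lists was chosen after their medians of 1.90 and 0.03 were seen, so the interval is not an independent test. A gain of scar-forming cells together with neuronal loss is a candidate explanation, as a hypothesis, and no test here separates cell number from expression per cell.

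The third pattern began with interferon-induced host genes among the lowest p-values of HBO against injury, such as Igtp (log2 change 1.40) and Nlrc5 (1.12), neither of which passed. On 19 other interferon-induced genes the median log2 change was 0.349, 17 were positive, and camera gave p = 0.000153 with the preset and p = 0.0358 with the estimated correlation, which met the prediction written beforehand. Library means were mixed: HBO replicates 2 and 3 stood at 0.591 and 0.801 on a centred log2 scale. HBO replicate 3 is also the library that lay apart from the others on the second principal component. HBO replicate 1 stood at -0.133, below all 3 injury libraries, and an exact two-sided permutation test gave p = 0.4 (smallest possible 0.1). The condition that each HBO library exceed each injury library was added after that was seen and was not met, so an interferon response to HBO stays open as a hypothesis. No single HBO library carried the median, which was 0.254 or more without any one of them, but the estimated-correlation p was 0.121 without HBO replicate 2, 0.0679 without HBO replicate 3, 0.0508 to 0.127 without any one control or injury library, and 0.00429 without HBO replicate 1.

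With 3 libraries against 3 there are 10 splits, too few for a share under 0.05. For changed features the real values were 1611, 4 and 1140 in injury against control, HBO against injury and HBO against control, the highest other splits gave 8, 10 and 10, and as many were reached by 1, 9 and 1 of the splits. For host-gene lists the real values were 6, 0 and 6, the highest others 5, 4 and 5, with 1, 10 and 1 splits as high. For the known long noncoding RNA list they were 1, 0 and 0, the highest others 0, 1 and 1, with 1, 10 and 10 splits as high. For features changed back the real value was 3, the highest other 8, with 7 splits as high.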
